A study of Caenorhabditis elegans with 9 samples.

How the data were processed

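Whole Caenorhabditis elegans were sequenced in 9 libraries, 3 in each of the groups OP (control), HFD (high fat) and FA (high fat with farrerol). Per the labels' protocols, total RNA was extracted with chloroform and the libraries were built with an NEBNext Ultra II RNA kit for Illumina. The genome build was WBcel235, per the submitters' processing notes. The aligner, the read counter and the use of strand are not given in the sources used here, so overlapping genes, antisense partners and near-identical copies can share reads. The labels do not say that the 3 libraries of a group came from separate cultures; p-values measure the spread between these libraries, which may be technical. Libraries of a group differed beyond sampling noise, with a chi-square of 18.6 to 85.8 per gene, so none looked like 1 library deposited more than once; this does not show that they came from separate cultures.

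The authors deposited 1 table of FPKM values for 46986 genes, with gene name, position, length and biotype, per the file headers. Its control columns are named OP50 with the numbers 1 to 3 and were matched to the samples titled OP by number, so the control values rest on this match. The values show how they were scaled: each FPKM times its gene length was a whole multiple of 1 step for 100% of the values above 0 in every library (tolerance 0.01 of a read), and the step corresponded to a library size equal to a median-of-ratios size factor times the geometric mean of the library totals. The reads recovered in this way summed to between 17514542 and 21419867 per library. A gene of 1 kilobase with 1 read has an FPKM of 0.0434 to 0.0597, and 3 reads, the fewest counted as a floor, correspond to 0.13 to 0.179 FPKM. Of the gene identifiers 46924 were found in the Ensembl annotation of WBcel235 (release 115), 99.82% of them at the same position. The 52 loci without a gene name held 0.0184% to 0.0293% of the reads and were left out of the tests; with the 32 that were expressed added to the genes tested, 0 of them were called in HFD against OP, 0 in FA against HFD and 3 in FA against OP. Picked after their values were seen, these 3 lie on chromosome I at 6144584 to 6145435 (log2 fold change -1.01, adjusted p = 0.0188), chromosome IV at 7053518 to 7054304 (-1.11, adjusted p = 0.0212) and chromosome III at 6628270 to 6631522 (0.79, adjusted p = 0.047). There were 0 further columns of values per sample.

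FPKM values are not read counts, so the tests were made with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a fitted mean-variance trend. Genes with an FPKM of at least 1 in at least 3 of the 9 libraries were kept, 14730 in all. A model of 3 group means was fitted to all 9 libraries, which leaves 6 residual degrees of freedom per gene before moderation. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Log2 fold changes are differences of group means of log2(FPKM + 1) with their standard errors and 95% intervals; for genes of low expression they are smaller than the ratio of the FPKM means. An adjusted p of a single gene in the text comes from this test, except where a library left out or the added loci are named.

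Before the data were examined, 42 gene lists were fixed, covering lipid metabolism, insulin-like and DAF-16 signalling, stress, detoxification, immunity, cuticle and moulting, general cell functions, and the tissues and germline contents of a whole animal. They were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation. Members were counted with p adjusted over all genes and over the list alone. The rule for named genes was also fixed then. It takes, for HFD against OP and for FA against HFD, the 8 largest changes in each direction among protein-coding genes with an adjusted p under 0.05, a mean of at least 5 FPKM in the higher group and no overlap between the groups, or the 5 lowest p values where none pass; up to 4 members with the lowest p of each list described; up to 10 genes called with opposite signs; and 14 genes of fat metabolism and DAF-16 signalling.

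Fold changes that share libraries were set beside 100 simulated data sets with the fitted spread and no effect. Their noise was drawn independently for each gene, whereas real genes vary together, so simulated ranges may be too narrow. The test was tried on simulated data made from the 14730 genes with 200 of them changed, 5 times for each comparison: 54.3% of 2-fold changes were recovered for HFD against OP, 48.1% for FA against HFD and 49% for FA against OP, with 5.4% to 5.9% false calls. The alternatives tried were other pseudocounts, filters on low values, scalings of the libraries, a spread from only the groups compared, the replicate number as a block, robust moderation, library weights, stricter thresholds, and leaving out each library in turn. limma's voom on the recovered reads, protein-coding genes with at least 10 reads in at least 3 libraries, scaling to total reads and the rotation test fry were added after seeing the data. Figures were drawn with matplotlib 3.10.9.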

Results

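Gene expression was measured by RNA sequencing of whole Caenorhabditis elegans in 9 libraries, 3 in each of 3 groups. OP was the control group, HFD the high-fat group, and FA a high-fat group that also received farrerol, a flavanone found in Rhododendron plants. Per the series title, fat accumulation was induced with citrate and the question was whether farrerol lowers it through DAF-16, the forkhead transcription factor of insulin-like signalling. Doses, strain and age of the animals are not given in the sources used here. The libraries held between 17514542 and 21419867 reads on genes, and 14730 of the 46986 genes in the table were expressed well enough to be tested. Values are FPKM (fragments per kilobase of gene, scaled to library size), given as mean ± SD over n = 3 libraries, and positions are those of the WBcel235 genome build.

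The first comparison, HFD against OP, asks what differed between the high-fat and the control group. Since age is not given, a difference in age cannot be told apart from the high-fat condition in the genes below. Among the largest increases, the saposin-like gene spp-9 (WBGene00004994, chromosome X, 11487784 to 11488203) went from 7.38 ± 2.84 to 1191 ± 573 FPKM, and cpt-3 (WBGene00021703, chromosome III, 2082819 to 2088314), a carnitine palmitoyltransferase of fatty acid oxidation, from 0.718 ± 0.155 to 252 ± 133 FPKM. In the other direction, all 86 measured sperm genes and all 27 oocyte and eggshell genes had negative changes, 34 and 19 of them past the threshold. Among the largest decreases, the collagen col-143 (WBGene00000716, chromosome V, 6835635 to 6836704) went from 73.3 ± 17.2 to 1.47 ± 0.653 FPKM and the lysosomal lipase gene lipl-5 (WBGene00022642, chromosome V, 385746 to 387740) from 378 ± 94.7 to 17.3 ± 9.19 FPKM.

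In all, 1083 genes passed an adjusted p of 0.05 in limma, 403 higher and 680 lower in HFD, and 596 of them differed by at least 2-fold. The smallest adjusted p was 2.41e-05. At an unadjusted p under 0.05 there were 3224 genes, where chance alone would give 736.5. The 3 HFD libraries did not overlap the 3 OP libraries in 29.3% of the tested genes, against 10% by chance. The first principal component held 51.8% of the variance and placed the OP libraries between -49.8 and -35.5, with the HFD libraries between 10.4 and 25.4. The count was 221 without OP replicate 2, 332 without OP replicate 3, 705 without HFD replicate 1, 326 without HFD replicate 2 and 652 without HFD replicate 3. The lean towards lower calls also depended on single libraries. The share higher in HFD was 37.2% with all libraries, 49.8% without OP replicate 2, 49.7% without OP replicate 3 and 41.6% to 45.4% without any other.

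Besides spp-9 and cpt-3, the genes with the largest increases were spp-12, far-3, irg-3, F48C1.9, R05H10.1 and F49C12.4. Expression of spp-12, another saposin-like gene, was 2.31 ± 1.16 FPKM in OP and 189 ± 136 in HFD (log2 fold change 5.68, SE 0.65, adjusted p = 0.00114). The fatty acid and retinol binding protein gene far-3 rose from 42.5 ± 7.14 to 1400 ± 705 FPKM (log2 fold change 4.87, SE 0.48, adjusted p = 0.000496), and the infection response gene irg-3 from 45.7 ± 12 to 1117 ± 339 FPKM (log2 fold change 4.57, SE 0.34, adjusted p = 7.68e-05). The uncharacterised genes F48C1.9, R05H10.1 and F49C12.4 reached 29.6 ± 26.5, 66.0 ± 23.9 and 13.6 ± 7.60 FPKM from OP means of 0.144, 4.18 and 0.190 FPKM. Their adjusted p values were 0.00455, 0.000456 and 0.00137.

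The largest decreases, besides col-143 and lipl-5, were in the collagens col-8 and col-119, the yolk gene vit-4, and C45B2.1, ZK813.1 and T22F3.11. Expression of col-8 fell from 156 ± 36.5 to 4.95 ± 2.42 FPKM (log2 fold change -4.77, SE 0.37, adjusted p = 0.000117) and that of col-119 from 512 ± 77.9 to 28.6 ± 25.6 FPKM (log2 fold change -4.44, SE 0.59, adjusted p = 0.00236). C45B2.1 fell from 98.3 ± 24.6 to 6.31 ± 3.93 FPKM and ZK813.1 from 41.7 ± 10.8 to 1.66 ± 1.63 FPKM, with adjusted p of 0.000496 and 0.00057. T22F3.11 averaged 61.6 ± 67.8 FPKM in OP and 2.37 ± 2.61 in HFD, an OP spread larger than its mean (adjusted p = 0.00971).

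**Figure D1:**
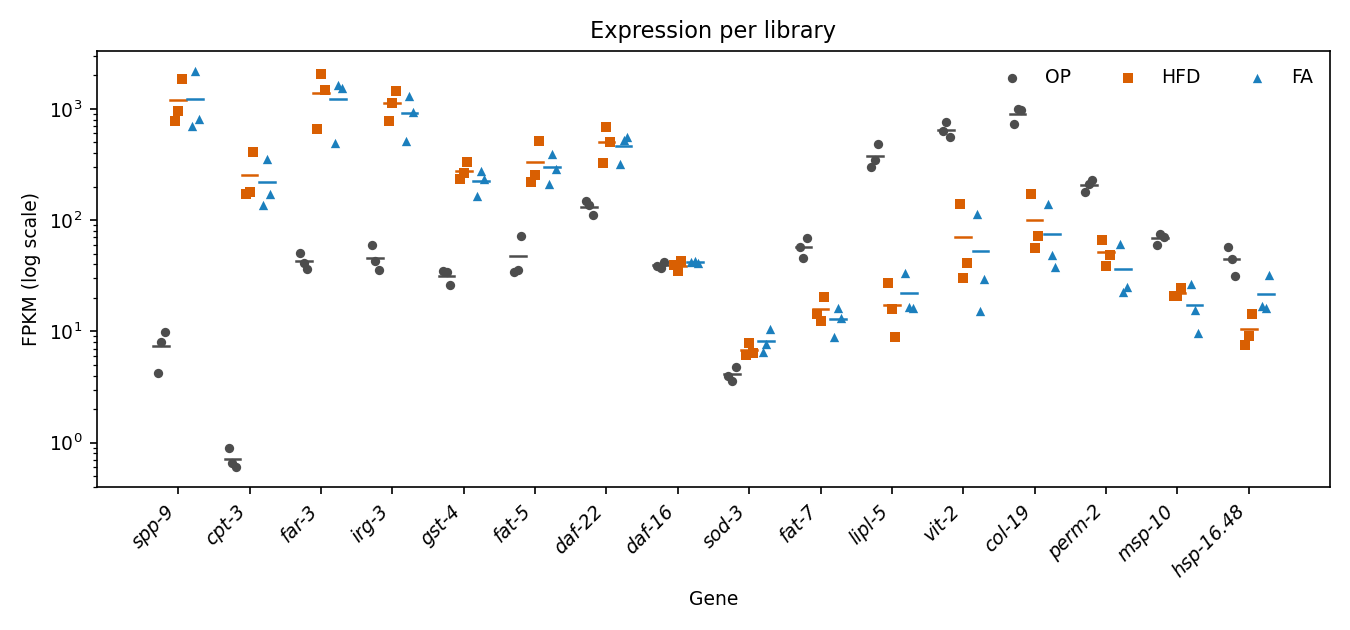
FPKM of 16 named genes in each library, on a log axis; circles are OP, squares HFD and triangles FA libraries, and lines are group means. HFD and FA libraries lie together and apart from OP for most genes shown, while daf-16 averaged 39.4, 39.0 and 42.1 FPKM in OP, HFD and FA.

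Of the 86 sperm genes 34 fell past the threshold over all genes tested and 65 when adjusted over the list alone. The list median was -0.97 on the log2 scale, and -1.04 to -0.89 over all alternatives. The count over all genes depended on which library was left out: 23 fell without OP replicate 1, 1 without OP replicate 2, 3 without OP replicate 3, and 10, 8 and 11 without HFD replicates 1, 2 and 3. The sperm-specific gene ssp-37 went from 4.71 ± 0.959 to 0.305 ± 0.107 FPKM, and the major sperm protein genes msp-65 and msp-10 from 121 ± 19.9 to 42.5 ± 1.89 and from 68.3 ± 7.54 to 22.1 ± 2.12 FPKM. Genes of the oocyte and eggshell list had a median of -1.01, and 19 of 27 fell (24 adjusted over the list alone); 2 fell without OP replicate 2, OP replicate 3 or HFD replicate 2, 12 without HFD replicate 1 and 7 without HFD replicate 3. Among them perm-2, an eggshell permeability barrier gene, went from 205 ± 25.5 to 51.1 ± 13.9 FPKM, and oma-2, a regulator of oocyte maturation, from 48.4 ± 14.2 to 18.6 ± 1.94 FPKM. Genes of the mitotic and meiotic germline had a median of -0.11, and -0.28 to -0.03 over all alternatives. Of these 30 genes 26 were lower and 0 passed. The major sperm protein genes are near-identical copies, so reads could be split among them and their single values are uncertain. Leaving out OP replicate 2 ended the calls of msp-65 and msp-10, with adjusted p up to 0.0526.

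limma's camera test with a preset inter-gene correlation gave an adjusted p of 1.56e-25 for the sperm list and 1.13e-15 for the oocyte and eggshell list; with an estimated correlation the adjusted p was 0.588 for both, and with fry, a rotation test against no change, 0.0752 for both, so neither list passed under these. Fry called 2 lists, lipases (lower) and glutathione S-transferases (higher), with an adjusted p of 0.014 each. Camera called 14 of the 42 lists with the preset correlation and 0 with an estimated one (smallest adjusted p = 0.567). Other groupings of these 6 libraries called up to 19 lists, so the groups below are described first by their members.

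Yolk and lipid carriers moved both ways: of 25 measured, 3 rose and 7 fell (6 and 7 adjusted over the list alone), and the list was not called (camera adjusted p = 0.682). The vitellogenin genes vit-2 and vit-5 fell from 648 ± 107 to 70.4 ± 59.9 FPKM and from 275 ± 76.0 to 24.2 ± 24.4 FPKM, with adjusted p of 0.014 and 0.0183, and vit-4 fell from 91.1 ± 31.3 to 9.44 ± 13.1 FPKM (adjusted p = 0.0293). HFD replicate 1 held 139 FPKM of vit-2, against 30.4 and 41.5 in the other 2 HFD libraries. The lipid-binding protein gene lbp-1 rose from 61.6 ± 9.83 to 169 ± 37.3 FPKM. The calls of vit-2 and lbp-1 were lost without OP replicate 2 or HFD replicate 2 (adjusted p up to 0.0679 and 0.0722), that of vit-5 also without OP replicate 3 or HFD replicate 3 (up to 0.086), and that of vit-4 without any 1 library but HFD replicate 1 (up to 0.12). The number of fallen carriers was 0 without OP replicate 2 or HFD replicate 2, 1 without OP replicate 3 or HFD replicate 3 and 3 without OP replicate 1, and that of risen ones 1 without OP replicate 2 and 2 without any other library.

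Of 22 genes of peroxisomal fatty acid oxidation, 6 rose, 1 fell and 15 did not pass (12 rose and 1 fell adjusted over the list alone), with a median of 0.56 and a camera adjusted p of 1.18e-05, 0.588 with an estimated correlation. Without OP replicate 2, OP replicate 3 or HFD replicate 2, 3 rose. The thiolase gene daf-22 rose from 132 ± 19.1 to 502 ± 176 FPKM, the hydratase gene maoc-1 from 74.2 ± 9.74 to 279 ± 92.7 FPKM, and the acyl-CoA oxidase gene acox-1.1 from 37.8 ± 10.2 to 174 ± 54.1 FPKM. Of 27 mitochondrial oxidation genes, 8 rose and 2 fell (12 and 5 adjusted over the list alone), and 5 rose without any 1 of the same 3 libraries. The acyl-CoA dehydrogenase gene acdh-10 rose from 142 ± 18.2 to 436 ± 71.6 FPKM, whereas ech-7 and hacd-1 fell from 131 ± 9.19 to 34.5 ± 7.52 FPKM and from 159 ± 110 to 12.4 ± 5.63 FPKM. The acyl-CoA synthetase gene acs-2 averaged 220 ± 201 FPKM in OP and 41.0 ± 18.5 in HFD and did not pass (adjusted p = 0.0935).

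The 3 Δ9 desaturases went different ways. Expression of fat-5, which acts on palmitate, rose from 47.3 ± 21.8 to 330 ± 160 FPKM (log2 fold change 2.76, SE 0.37, adjusted p = 0.00249). Expression of fat-7, which acts on stearate, fell from 57.3 ± 11.3 to 15.7 ± 4.22 FPKM (log2 fold change -1.81, SE 0.24, adjusted p = 0.00236). Its near copy fat-6 averaged 432 ± 140 in OP and 221 ± 83.0 in HFD and did not pass (adjusted p = 0.0545). In the list of 16 desaturases and elongases, 1 rose and 3 fell (2 and 4 adjusted over the list alone), and elo-2 fell from 165 ± 13 to 68.01 ± 23.8 FPKM. Of 19 lipases, 1 rose and 3 fell (1 and 7 adjusted over the list alone); without any 1 library 0 rose and 1 or 2 fell, and lipl-5 passed each time. Among the 18 genes of triglyceride storage, 2 rose, the lipid droplet gene plin-1 (87.7 ± 4.4 to 168 ± 36.7 FPKM) and the acyltransferase gene dgat-2 (22.9 ± 7.24 to 52.4 ± 16 FPKM); 3 rose and 0 fell when adjusted over the list alone. The call of plin-1 was lost without any 1 library but HFD replicate 1 (log2 fold change 0.74 to 1.05, adjusted p up to 0.0997) and that of dgat-2 without any but OP replicate 1 or HFD replicate 2 (0.93 to 1.43, adjusted p up to 0.139). Fatty acid synthesis had 0 of 11 genes past the threshold, also when adjusted over the list alone. In it pod-2 (acetyl-CoA carboxylase) changed by -0.51, fasn-1 (fatty acid synthase) by 0.25, and acly-1 and acly-2 (ATP citrate lyases) by 0.39 and -0.32 on the log2 scale. Of the 29 genes of the citrate cycle, glyoxylate cycle and citrate transport, 0 passed over all genes or adjusted over the list alone.

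Glutathione S-transferase and oxidative stress genes rose more often than they fell. Of 44 glutathione S-transferase genes, 13 rose and 2 fell (16 and 2 adjusted over the list alone), with a median of 0.38 (camera adjusted p = 9.73e-07, and 0.567 with an estimated correlation); 6 rose without OP replicate 2 and 7 without OP replicate 3 or HFD replicate 2. Expression of gst-4 rose from 31.6 ± 4.98 to 277 ± 53.1 FPKM and that of gst-33 from 6.20 ± 0.704 to 38.5 ± 9.75 FPKM. Of 26 oxidative stress genes, 5 rose and 0 fell (9 and 1 adjusted over the list alone), led by the glutathione peroxidase gene gpx-1, from 38.9 ± 5.81 to 304 ± 90.1 FPKM. Of these, 1 rose without any 1 OP library or HFD replicate 2, 2 without HFD replicate 3 and 4 without HFD replicate 1, and gpx-1 passed each time. Infection response genes moved both ways, with 7 of 42 higher and 5 lower (10 and 8 adjusted over the list alone), and 3 to 6 higher and 2 to 5 lower without 1 library, fewest without OP replicate 2. Among them irg-5 rose from 15.8 ± 4.01 to 137 ± 63.6 FPKM, dod-24 rose from 26.8 ± 15 to 235.4 ± 78.5 FPKM, and dod-22 fell from 10.5 ± 2.18 to 2.04 ± 0.326 FPKM.

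Of 21 heat shock genes 6 fell and 1 rose (11 and 3 adjusted over the list alone). Without HFD replicate 3 again 6 fell, but without any other library 1 fell. The camera call (adjusted p = 0.0289) was lost without OP replicate 1 (0.128) and with an estimated correlation (0.787). Expression of hsp-16.48 went from 44.4 ± 12.7 to 10.4 ± 3.59 FPKM (adjusted p = 0.00482, and up to 0.0285 without 1 library), while hsp-12.3 rose from 6.41 ± 0.885 to 26.2 ± 9.52 FPKM. Components of the insulin pathway were examined at the RNA level. The level of daf-16 was 39.4 ± 2.47 FPKM in OP and 39.0 ± 4.02 in HFD (log2 fold change -0.02, SE 0.12, adjusted p = 0.956), and daf-2, the insulin receptor gene, changed by -0.10 (adjusted p = 0.83). Of 20 pathway genes 1 fell and 0 rose; adjusted over the list alone, 0 passed, and 0 fell without any 1 library but OP replicate 1. Of 26 insulin-like peptide genes 18 were higher, with a median of 0.29 (0.15 to 0.43 over all alternatives, lowest without HFD replicate 1). Among them 1 passed (1 adjusted over the list alone), ins-30, from 3.54 ± 0.595 to 8.21 ± 0.831 FPKM. The camera call of the peptide list (adjusted p = 0.0314) was lost without OP replicate 2 (0.0753), HFD replicate 1 (0.0851) or HFD replicate 2 (0.0653) and with an estimated correlation (0.787). Among genes described as raised by active DAF-16, 2 of 29 rose and 7 fell (7 and 9 adjusted over the list alone), and among those described as lowered by it 2 of 10 rose and 4 fell (2 and 7 adjusted over the list alone). Without 1 library 1 to 6 of the former fell (6 without HFD replicate 3, 1 or 2 otherwise) and 1 to 5 of the latter (5 without HFD replicate 1, 1 without OP replicate 2 or HFD replicate 2). The 6 fallen heat shock genes, all hsp-16 genes, were among the 7 fallen genes described as raised by DAF-16. The other was aqp-1. Both counts of fallen genes therefore rest largely on the same hsp-16 genes. The superoxide dismutase gene sod-3 averaged 4.11 ± 0.6 and 6.82 ± 0.978 FPKM (adjusted p = 0.0746). The changes of sbp-1, nhr-49, atgl-1 and lipl-4, regulators and lipases of fat metabolism, did not pass, with adjusted p of 0.462, 0.273, 0.404 and 0.188.

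The comparison of FA with HFD asks what farrerol added under the high-fat condition. Several genes called in HFD against OP had FA means closer to those of HFD than of OP: spp-9 averaged 1235 ± 840 FPKM in FA, far-3 1225 ± 632, col-143 1.73 ± 1.29 and vit-2 52.8 ± 53.5 FPKM. No protein-coding gene passed in limma. The daf-16 transcript averaged 42.1 ± 0.691 FPKM in FA, a log2 difference of 0.11 from HFD with a 95% interval from -0.15 to 0.37, and sod-3 averaged 8.25 ± 2.02 FPKM, a log2 difference of 0.23 with an interval from -0.18 to 0.64.

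The single gene called was 21ur-9873 (WBGene00170474, chromosome IV, 5891296 to 5891316), a piRNA locus of 21 bases, named here after its values were seen. It had 1 read in each HFD library and 0 reads in each FA and OP library (adjusted p = 0.0136). At an unadjusted p under 0.05 there were 368 genes, where chance alone would give 736.5, and the groups did not overlap in 5.1% of genes, against 10% by chance. The low number depended on FA replicate 1. Without it 1113 of 14622 tested genes had an unadjusted p under 0.05, and without any other library 244 to 448 did. The 5 protein-coding genes with the lowest p, given as not passing, were C42C1.3, F53B6.13, F28F5.4, Y50E8A.10 and C01B10.44, with log2 differences of -1.04, 0.90, 0.74, -0.62 and -0.77 and an adjusted p of 1 each. In simulated libraries of this size and spread the same test recovered 10.7% of genes changed by 1.5-fold, 48.1% of those changed by 2-fold and 89.1% of those changed by 4-fold. Changes below 2-fold were therefore mostly not detectable with 3 libraries per group.

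None of 12 further genes of fat metabolism and insulin signalling, fixed for inspection beforehand, passed, and every interval included 0. The log2 differences between FA and HFD were -0.09 for fat-5 (95% interval -0.90 to 0.73), -0.12 for fat-6 (-0.72 to 0.48), -0.28 for fat-7 (-0.81 to 0.25), 0.08 for sbp-1 (-0.38 to 0.53), 0.04 for nhr-49 (-0.33 to 0.42) and 0.01 for pod-2 (-0.40 to 0.42). For fasn-1 the difference was 0.01 (-0.31 to 0.34), for the triglyceride lipase gene atgl-1 0.10 (-0.30 to 0.51), for the lysosomal lipase gene lipl-4 0.27 (-0.18 to 0.73), for acs-2 -0.07 (-1.58 to 1.44), for vit-2 -0.58 (-2.06 to 0.90) and for daf-2 0.11 (-0.33 to 0.55).

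Some gene groups leaned one way as groups, with 0 members called in any list, also when adjusted over the list alone. Of 21 heat shock genes 19 were higher in FA, with a median of 0.41, and hsp-16.48 and hsp-16.2 averaged 21.7 ± 9.02 and 218 ± 128 FPKM, against 10.4 ± 3.59 and 105 ± 45.5 in HFD. The list medians of the FA libraries relative to OP were -0.40, -0.24 and 0.22, and those of the HFD libraries -0.56, -0.65 and -0.60. FA replicates 2 and 3 stood apart: on the second principal component (10.8% of the variance) they lay at -26.1 and 30.6, and ribosomal protein genes took 18.11% and 12.91% of their reads, against 14.09% to 16.7% in the other libraries. Without FA replicate 3 the median was 0.27. The hsp-16 genes are close copies of one another, so reads could be split among them. Genes described as raised by active DAF-16 had a median of 0.21, which was 0.08 without FA replicate 2 and 0.34 without FA replicate 1. This list shares 17 of its 30 listed genes with other lists, and the same hsp-16 genes stood at its head. Sperm and oocyte genes had medians of -0.33 and -0.33; without FA replicate 1 these were -0.71 and -0.51, and without FA replicate 3 the sperm median was -0.11.

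Camera with the preset correlation called 7 lists in this comparison, with adjusted p of 6.33e-11 for heat shock, 3.97e-06 for genes raised by DAF-16, 1.99e-15 for sperm, 5.53e-12 for oocyte and eggshell, 0.00166 for nuclear receptors, 0.00669 for collagens and 0.00897 for the mitochondrial genome. With an estimated correlation none was called (smallest adjusted p = 0.714), nor with the rotation test fry (smallest adjusted p = 0.992). Calls were lost without HFD replicate 1 for genes raised by DAF-16 (adjusted p = 0.0656), nuclear receptors (0.287) and collagens (0.362), without FA replicate 3 for nuclear receptors (0.901) and the mitochondrial genome (0.74), and for the latter also without HFD replicate 2 (0.126) or FA replicate 1 (0.198). Collagens passed in the other direction without FA replicate 3, with a median of 0.07 (adjusted p = 0.0351), against -0.10 with all libraries. Other groupings of the same 6 libraries called up to 20 lists, more than the real one.

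**Figure D2:**
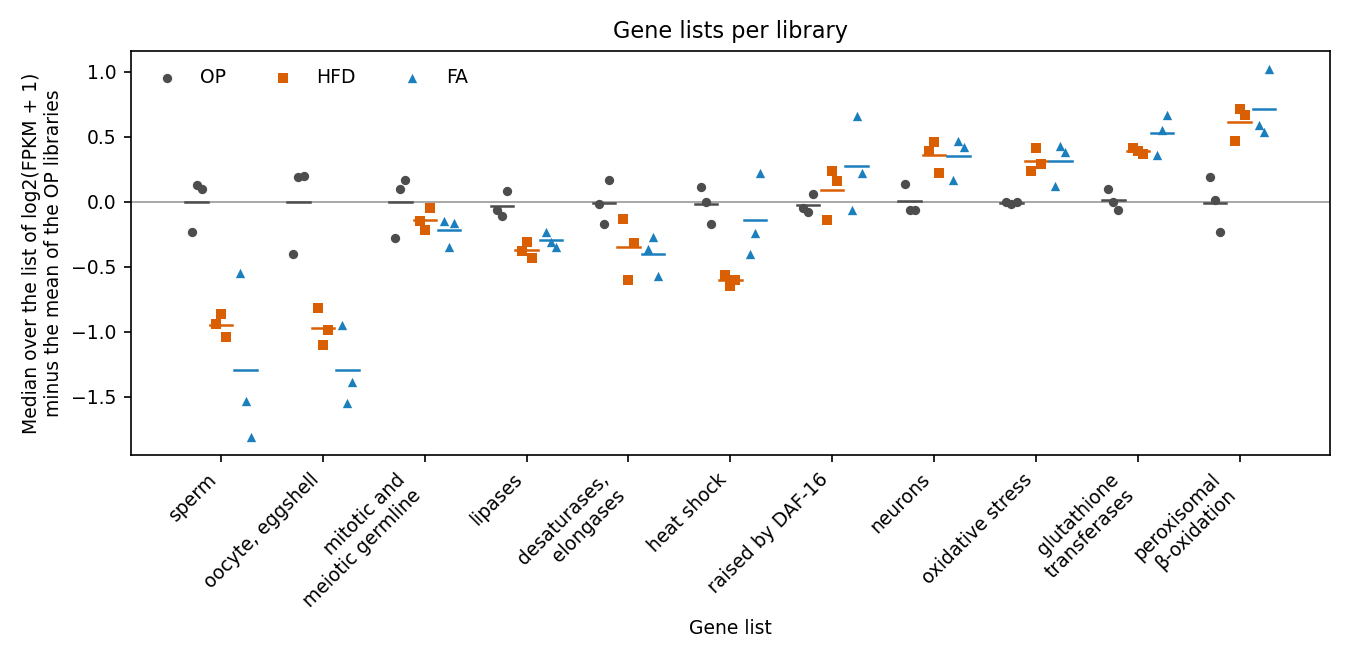
Median of log2(FPKM + 1) over each gene list minus the mean of the 3 OP libraries, 1 point per library; circles are OP, squares HFD and triangles FA, and lines are group means. Sperm medians lay between -1.04 and -0.86 in HFD and between -1.81 and -0.55 in FA, and heat shock medians between -0.65 and -0.56 in HFD and between -0.40 and 0.22 in FA.

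The third comparison set FA against OP, and with it whether the treated animals moved back towards the control. The FA libraries lay on the same side of OP as the HFD libraries, between 5.3 and 38 on the first principal component. In limma 2146 genes were called, 679 higher and 1467 lower in FA, and 1019 of them changed at least 2-fold. The called genes included spp-9 (log2 fold change 7.07, adjusted p = 3.96e-05), cpt-3 (6.89, adjusted p = 2.29e-05), fat-5 (2.67, adjusted p = 0.00217), fat-7 (-2.09, adjusted p = 0.000948) and vit-2 (-4.07, adjusted p = 0.00403). Both sod-3 (0.84, adjusted p = 0.0133) and fat-6 (-1.1, adjusted p = 0.0217) passed here and not in HFD against OP; the difference between the groups did not pass for either. The count was 883 without OP replicate 2, 1072 without OP replicate 3, 1140 without FA replicate 2 and 1405 without FA replicate 3.

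Sperm, oocyte, glutathione S-transferase and peroxisomal genes went the same way as in HFD. Sperm genes had 66 of 86 lower and 0 higher (74 and 0 adjusted over the list alone; median -1.28; 35, 39 and 38 lower without OP replicate 2, OP replicate 3 or FA replicate 2), and oocyte and eggshell genes 22 of 27 lower (25 adjusted over the list alone; median -1.3). Of 44 glutathione S-transferase genes 17 rose and 0 fell (21 and 2 adjusted over the list alone), and of 22 peroxisomal oxidation genes 11 rose and 0 fell (12 and 1 adjusted over the list alone). Without 1 library 8 to 19 of the former and 4 to 10 of the latter rose, fewest without OP replicate 2. Camera called 13 lists with the preset correlation and 0 with an estimated one (smallest adjusted p = 0.392), and other groupings of these libraries called up to 18. Fry called 6: glutathione S-transferases (adjusted p = 0.00593), peroxisomal oxidation (0.0443) and oxidative stress (0.0443) higher, and lipases (0.0279), oocyte and eggshell (0.0279) and sperm (0.031) lower. Heat shock genes and genes described as raised by active DAF-16, lists that share hsp-16 genes, had other counts than in HFD. Of 29 such DAF-16 genes 6 rose and 3 fell (7 and 3 adjusted over the list alone), against 2 and 7 in HFD, and the list was not called (camera adjusted p = 0.23). Of 21 heat shock genes 2 rose and 1 fell (2 and 1 adjusted over the list alone), against 1 and 6 in HFD; 0 members of either list passed between FA and HFD. These counts changed with the library left out. Of the DAF-16 genes 2 rose and 2 fell without OP replicate 1, 1 and 0 without OP replicate 2, 3 and 2 without OP replicate 3, 5 and 1 without FA replicate 1, 2 and 1 without FA replicate 2, and 3 and 6 without FA replicate 3. Of the heat shock genes 1 or 2 rose without any 1 library, and 6 fell without FA replicate 3, 1 without OP replicate 3 and 0 without any other. Expression of hsp-16.48 averaged 44.4 ± 12.7 FPKM in OP and 21.7 ± 9.02 in FA (adjusted p = 0.0464).

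Of the genes called in HFD against OP, 377 were also called higher and 632 also called lower in FA against OP, and 0 were called in opposite directions. Independent lists would share 18.6 and 67.7, which leaves out the shared OP libraries, and 100 simulations of groups without any effect that share them gave 0 and 0, which leaves out the effects. Across genes, which are not independent replicates, the fold changes of both groups against OP correlated with r = 0.926; groups without any effect that share the OP libraries gave 0.501 in 100 simulations. The covariance was 0.293, against 0.027 simulated. No division of 3 OP libraries leaves 2 on each side, so part of the excess in shared calls may come from the shared controls; in the covariance, where sharing adds the same amount with or without effects, the difference was 0.266. Over the 1083 called genes the change in FA was a median of 1.08 times that in HFD.

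A return towards OP was looked for gene by gene. Of the 1083 genes, 402 (37.1%) had a difference between FA and HFD directed back towards OP. An FA group identical to HFD gave 64.4% in simulation, with a range from 61.8% to 67.2%. The simulated noise was independent between genes, whereas real genes vary together (estimated correlation 0.636 among sperm and 0.822 among oocyte genes). That range is therefore too narrow to decide whether 37.1% differs from an identical group. The change in HFD and the further change in FA correlated across genes with r = 0.077, where simulated groups without any effect that share the HFD libraries gave -0.5. Those groups hold no HFD effect, which widens the spread of the change in HFD, so both r values cannot be compared. The covariance, to which sharing adds the same amount with or without an effect, was 0.00931 against -0.0269. The number of genes called in both comparisons with opposite signs was 1, the piRNA locus 21ur-9873, and independent lists would give 0.0274. That value leaves out the shared HFD libraries, which favour opposite signs. An FA group identical to HFD gave 0 opposite calls in each of 100 simulations that share them. These drew noise with the fitted spread, not whole reads, so they do not show how often 0 and 1 reads give such a call.

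**Figure D3:**
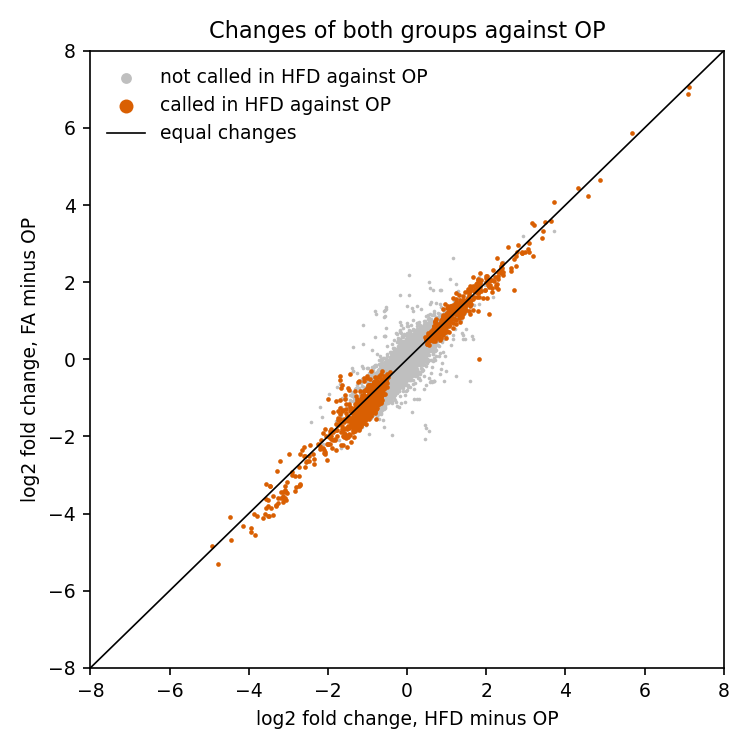
Log2 fold change of each of the 14730 tested genes in FA minus OP (vertical axis) against HFD minus OP (horizontal axis), from limma; orange points are the 1083 genes called in HFD against OP and the line marks equal changes. The called genes lie along the line, with 1082 of 1083 on the same side of 0 in both comparisons.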

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

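Tests with voom, the filter on reads, scaling to total reads and fry were chosen after seeing the data. Genes called in HFD against OP numbered 472 with no filter on low values, 3302 with library weights, 1659 with only the 2 groups in the fit, 596 at 2-fold or more and 269 at an adjusted p under 0.01. Leaving out 1 library gave 221 to 867, with 221 without OP replicate 2, 332 without OP replicate 3, 705 without HFD replicate 1, 326 without HFD replicate 2 and 652 without HFD replicate 3. For FA against OP the numbers were 1424 with no filter, 1019 at 2-fold or more and 818 at an adjusted p under 0.01, and 883 to 2550 without 1 library (883 without OP replicate 2, 1072 without OP replicate 3, 1140 without FA replicate 2, 1405 without FA replicate 3). The thresholds and the fits with fewer libraries or more genes tested differ by construction; for the library weights, which favoured OP replicate 2 (weight 5.07), the cause was not tested. For FA against HFD, and for genes called with opposite signs, the single call became 0 with a pseudocount of 0.1, the filter at 5 FPKM, the replicate block, voom, the filter on reads and only the 2 groups in the fit, in which the locus of 21 bases lost its call or was not tested; FA against HFD also gave 0 at an adjusted p under 0.01. Without 1 library both counts ran from 0 to 2.

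Replicate numbers were not taken as pairs, since not every same-numbered pair correlated above 0.1: deviations of same-numbered libraries correlated between -0.23 and 0.30, with 2 of 9 pairs above 0.1, and 4 of 9 libraries matched their own number best in another group. Replicate 1 of HFD and FA correlated at r = 0.9861, above every pair within a group (at most 0.9842), and the mean log2 of the vitellogenins was 5.68, 2.81 and 3.49 in HFD and 5.22, 2.21 and 3.04 in FA replicates 1 to 3. With the number as a block, 837, 0 and 1868 genes were called in HFD against OP, FA against HFD and FA against OP.

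Lists called numbered 0 in every comparison with an estimated correlation, and 2, 0 and 6 with fry. Without 1 library they ran from 11 to 15, 5 to 15 and 10 to 14; for FA against HFD there were 12 without HFD replicate 2, 15 without HFD replicate 3, 13 without FA replicate 1 and 12 without FA replicate 3. Ribosomal protein genes lost their call under quantile normalization, where camera gave the other direction without passing, with a median of -0.02 in HFD against OP and 0 in FA against OP; the cause was not tested. Without 1 library their median ran from 0.08 to 0.2 and from -0.01 (without FA replicate 2, adjusted p = 0.993) to 0.4 (without FA replicate 3), against 0.15 and 0.16. Without 1 library the medians in FA against HFD ran from -0.11 to 0.15 for the respiratory chain, -0.31 to 0.07 for collagens and -0.17 to 0.27 for ribosomal proteins, changing sign. Of the called genes picked for naming in HFD against OP, 40 of 98 lost the call without OP replicate 2 and none of the 1928 values of called genes under all alternatives reversed; 233 fell short of the threshold. The tests on reads planned for a table of counts were not run, since the table holds none. Depth limits genes near the floor of 3 reads, as the piRNA locus shows.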

Other observations

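The tests of the whole germline and of the reads behind the single call were chosen after the result was seen. In several other gene families some members passed in HFD against OP, in both directions, while camera called none of these lists (adjusted p of 0.767 for glucuronosyltransferases, 0.878 for cytochrome P450, 0.207 for nuclear receptors, 0.0798 for collagens and 0.767 for moulting and hedgehog-related genes). For scale, 1083 of all 14730 tested genes passed. Nuclear receptors passed less often than that, and moulting and hedgehog-related genes little more often. The counts moved when 1 library was left out: 3 to 6 glucuronosyltransferase, 2 to 4 cytochrome P450, 1 to 6 nuclear receptor, 3 to 14 collagen and 3 to 11 moulting and hedgehog-related genes rose, fewest without OP replicate 2, and 0 to 4, 1 to 4, 1 to 2, 16 to 29 and 1 to 6 fell. Of 60 measured UDP-glucuronosyltransferase genes, which conjugate foreign compounds, 5 rose and 2 fell (7 and 4 adjusted over the list alone); ugt-1 rose from 3.65 ± 0.751 to 18.5 ± 6.44 FPKM and ugt-16 from 6.20 ± 2.73 to 26.5 ± 3.57 FPKM (n = 3). Cytochrome P450 genes went both ways, with 5 of 51 higher and 5 lower (5 and 6 adjusted over the list alone), such as cyp-14A5 at 6.05 ± 1.57 and 14 ± 2.02 FPKM and cyp-34A8 at 6.59 ± 0.48 and 3.12 ± 0.172 FPKM in OP and HFD. Among 168 nuclear receptor genes, 4 rose and 3 fell (4 and 2 adjusted over the list alone): nhr-11 rose from 2.32 ± 0.194 to 9.91 ± 1.84 FPKM and nhr-8 fell from 14.9 ± 1.29 to 6.23 ± 1.03 FPKM.

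Cuticle genes were divided. Of 156 collagens 16 rose and 27 fell (29 and 33 adjusted over the list alone). The collagen col-19, a marker of the adult hypodermis, fell from 900 ± 150 to 99.5 ± 62.5 FPKM and col-140 from 1263 ± 266 to 150 ± 80.2 FPKM, while col-10 rose from 981 ± 242 to 2300 ± 542 FPKM, a call lost without OP replicate 2, OP replicate 3, HFD replicate 1 or HFD replicate 2 (adjusted p up to 0.145). Of 78 moulting and hedgehog-related genes 4 rose and 3 fell (8 and 5 adjusted over the list alone). The neighbouring genes grd-10, grd-13 and grd-3 on chromosome IV rose together, from 39.4 ± 6.59 to 141 ± 33.5, from 39.0 ± 15.2 to 135 ± 33.7 and from 67.2 ± 8.48 to 160 ± 32.9 FPKM, and wrt-8 fell from 12.15 ± 3.06 to 1.73 ± 0.197 FPKM. All 26 neuronal genes were higher in HFD, by a median of 0.34, but 2 passed, and 1 or 0 without any 1 library (4 adjusted over the list alone; camera adjusted p = 3.41e-06, and 0.588 with an estimated correlation). Other somatic lists leaned the same way. Of 16 pharynx genes 14 were higher, with a median of 0.34 and 1 past the threshold, which became 2 without HFD replicate 3 and 0 without any other library (camera adjusted p = 0.0025, and 0.763 with an estimated correlation), and of 23 body muscle genes 19 were higher, with a median of 0.21 and 0 past it (0.0371, and 0.949). The muscle call was lost without OP replicate 3 (0.681), HFD replicate 1 (0.272) or HFD replicate 2 (0.163). The muscle median ran from 0.12 without OP replicate 3 to 0.33 without HFD replicate 3. Intestine and hypodermis lists had medians of 0.14 and 0.11 and were not called (0.471 and 0.682). Over the alternatives these medians ran from 0.02 to 0.29 and from 0.03 to 0.21. The lowest camera adjusted p among the alternatives was 0.0155 for the intestine and 0.326 for the hypodermis.

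Sperm and oocyte genes were lower in HFD than in OP in all 3 HFD libraries. Under total-read scaling and quantile normalization the less negative of both list medians stayed at -0.95. Total-read scaling moved the median of all tested genes only from 0.014 to -0.025. A shift of this size could not have lifted the lists to near 0, so that outcome decides nothing about library scaling. The fall did hold under quantile normalization. A bias by gene length was argued against, since the less negative of both list medians stayed at -0.98 after a trend on length was removed. Sperm genes are short (median 384 bases, against 1795 for oocyte genes and 1297 for all tested genes). A smaller share of the whole germline in the RNA would lower the mitotic and meiotic germline list by about as much. Its median was -0.11 with an interquartile range of 0.19. Over the alternatives the median ran from -0.28 to -0.03, with a camera adjusted p from 1.5e-05 to 0.705 at the preset correlation, and 26 of 30 members were lower. In FA against OP this list was called lower (median -0.19, camera adjusted p = 0.0163). That call was lost without OP replicate 2 (0.0716), OP replicate 3 (0.233) or FA replicate 2 (0.157). It was also lost with an estimated correlation (0.981) and with fry (0.437). The germline list thus fell less than the gamete lists, but a smaller germline share as part of the cause stays open. Somatic lists leaned the other way, with medians of 0.34 for neurons, 0.34 for the pharynx and 0.21 for body muscle. An effect of the high-fat condition on gametes stays open as untested, and so does a difference in age, which is not given.

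In camera with the preset correlation, heat shock genes were called higher in FA than in HFD as a list. Other groupings of the same 6 libraries called up to 20 lists, so a pass under this setting says little by itself. The number of heat shock genes called lower in FA than in OP depended on FA replicate 3 (1 with it, 6 without). Called or not, 12 of 21 were lower in FA than in OP with all libraries (list median -0.31). That FA replicate 3 alone decides the camera call between FA and HFD was argued against. Without it the median was 0.27 and the camera adjusted p 2.44e-05. Over the alternatives at the preset correlation the adjusted p ran from 4.87e-12 to 2.44e-05. With fry, which tests against no change, it was 0.992. The camera adjusted p of 0.714 with an estimated correlation shows that the call rests on treating the genes as nearly independent, and most of the listed genes at its head are close copies. A handling difference between animals at collection could raise the same genes and stays open beside an effect of farrerol; neither was tested.

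The gene called between FA and HFD may be a matter of a few reads on a very short gene. The highest number of reads in any library was 1, and in the HFD libraries a locus of 21 bases turns 1 read into 2.29 to 2.84 FPKM. No biological explanation was tested for it.

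Each comparison of 3 against 3 libraries has 10 splits, so no share of splits can fall under 0.1. For HFD against OP, 1 of the 10 splits, the real one, called as many as the 1083 genes, and the highest of the others called 2. For FA against OP it was also 1, with 2146 genes against at most 5. For FA against HFD, 6 of the 10 splits called as many as the real 1, up to 4. Lists behaved differently: 5 splits called as many as the 14 lists of HFD against OP (highest other 19), 9 as many as the 7 of FA against HFD (highest other 20), and 7 as many as the 13 of FA against OP (highest other 18).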
